A study of Caenorhabditis elegans with 20 samples.

How the data were processed

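Transcript levels were measured in 20 samples of the nematode Caenorhabditis elegans with an Affymetrix C. elegans genome array. The animals came from 3 strains, each with and without Orsay virus, a positive-strand RNA virus that infects the intestine of this worm in the wild. N2 is the laboratory reference strain. JU1580 is a wild isolate. The strain named rde-1 lacks a working RDE-1, an Argonaute protein needed for RNA interference. Per the labels' protocols, worms were grown at 20 °C on a laboratory Escherichia coli strain, L4 larvae were picked, virus or a control solution was added 24 hours later, and total RNA of the mixed-stage population was taken with Trizol 4 days after that. There were 4 uninfected and 4 infected N2 samples, and 3 uninfected and 3 infected samples of each of the other strains. The strain label of 1 uninfected rde-1 sample has an extra allele prefix that the other rde-1 samples lack, and the sample was kept in that group.

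The deposited values are log2 probe set intensities of all 20 arrays in a single table. Per the submitters' processing notes, they were made with RMA, which corrects background, equalises the distributions of the arrays and summarises the probes of each probe set, in the affy package, with no version stated. Whether all arrays were processed in 1 run was not given in the sources used here, nor was the probe set definition. The array medians lay between 5.62 and 5.82 and single values between 2.50 and 14.0. No detection call per probe set was used here, so a level near the lower end of that range cannot be told from background. Arrays have no read depth, and their number limits the precision. No further normalization was done.

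Of the 22625 probe sets, 77 controls were left out and 22548 were tested. Gene symbols came from the platform annotation, matched through Entrez gene numbers to a gene table of the assembly WBcel235, which was used only for names and for which genes lie beside each other. Of the tested probe sets, 20766 named 1 gene, 887 named several and 895 named none. A match was found for 20701 of the single-gene probe sets, no symbol needed an update, and 65 stayed unmatched and kept their old symbol. Coordinates are not given, because no genome build is named for the array. The brightest probe set over all arrays stood for each of 17138 genes, 2966 of which had more than 1. Probe sets with suffixes other than plain _at, which can read related transcripts, were kept, and 15837 probe sets were plain.

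Group means were fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 14 residual and 3.54 prior degrees of freedom). The comparisons were infected minus uninfected in each strain, the differences between these effects for each pair of strains, and uninfected JU1580 or rde-1 minus uninfected N2, 8 in all. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 in limma's moderated two-sided test, with no fold threshold. Every adjusted p given for a gene is limma's, adjusted over the 22548 probe sets of that comparison. Changes are differences of log2 means ± SE from this fit, and levels are means ± SD. The SE of a median over genes is taken across those genes. It treats them as independent and leaves out the spread between arrays. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Over all arrays the values of a group's samples were identical for at most 8 probe sets, so no array was a copy of another.

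The tests, the samples in each fit, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named the 12 largest rises and falls past the threshold for each infection effect, the 8 largest each way for the other comparisons, up to 4 members of each list with the smallest p in each comparison, and the genes rde-1, drh-1 and dcr-1 everywhere. The 28 lists were written from memory of the literature. Whether that literature draws on this series was not checked, so the list tests may not be independent of these data. They cover the pals family, other genes of the intracellular infection response, antiviral RNA interference, Argonautes, targets of the Argonaute ERGO-1, F-box A, F-box B and C, MATH and BATH genes, C-type lectins, lysozymes and antimicrobial peptides, and the bacterial infection response. They also cover small heat shock genes, cytochrome P450, UGT and GST genes, vitellogenins, fatty acid desaturation and elongation, collagens, molting, ribosomal proteins, histones, and mitochondrial and ER stress. Stage and tissue lists were sperm, oocyte and eggshell, germline, early embryo, intestine, body wall muscle and neuron. The pals list and the other intracellular response list share 2 genes, pals-11 and pals-12.

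Lists were tested with camera in limma at a preset inter-gene correlation of 0.01, two-sided, adjusted by Benjamini-Hochberg over the 28 lists of a comparison. Camera asks whether a list's genes move more than other genes. It was repeated with a correlation estimated from the data. The fry test, which asks whether the genes of a list move on balance 1 way and does not set them against other genes, was run beside it. For each list the calls over all probe sets are given beside those adjusted over the list alone. Overlaps of calls were tested with a one-sided Fisher's exact test per direction. The 3 infection effects have no array in common and share only the estimate of the spread.

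The fit was tested on simulated data with the mean level and pooled spread of each probe set and 100 probe sets changed at each size. For 2-fold changes it recovered 84% in N2, 72% in JU1580 and 76% in rde-1, and 49%, 49% and 42% for the strain differences JU1580 minus N2, rde-1 minus N2 and JU1580 minus rde-1. For 4-fold changes recovery was 98%, 98% and 100% in the strains and 90%, 97% and 93% for those differences. For the uninfected comparisons it was 84% and 75% at 2-fold and 100% at 4-fold. Between 5 and 13 false calls were made per comparison. The simulated noise was independent between genes and equally wide in all groups. It held no shifts of whole arrays such as those in germline transcripts described below. These recovery and false call figures may therefore not hold for the real arrays.

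Alternatives were a fit of the compared arrays alone, the replicate number as a block, median centring, quantile normalization, filters on dim probe sets, a trend and robust prior, array weights, plain probe sets only, a 2-fold threshold, other set tests and leaving out each array in turn. An added fit left out JU1580 infected 3, far from its group on the first principal component, and rde-1 infected 2, far from its group on the fourth but not on the first 2. N2 uninfected 1 and JU1580 uninfected 1, which also lie apart from their groups on the first component, were kept in that fit and left out only singly. Another held the mean level of the oocyte and germline lists as a covariate. These additions were chosen after the data were seen. Plots were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.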

Results

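The series set infected against uninfected animals in N2, which its design text calls resistant to Orsay virus, and in JU1580 and rde-1, which it calls sensitive. Each of the 20 samples was read on 1 array, and pairs of arrays correlated at r = 0.899 to 0.997 across probe sets. The first principal component held 45.8% of the variance, the second 15.1% and the third 8.52%. Control probe sets at the 3' and 5' ends of the same transcripts differed by 0.900 to 1.46 on the log2 scale over the arrays. The highest value, 1.46, was that of N2 uninfected 2, and the other arrays lay between 0.900 and 1.23.

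The rde-1 gene, which encodes the Argonaute that starts the small interfering RNA pathway, was read at 8.69 ± 0.11 (SD, n = 4) in uninfected N2 and 8.74 ± 0.14 (n = 3) in the uninfected rde-1 strain. Its level was 8.64 ± 0.11 (n = 3) in uninfected JU1580. A transcript carrying a small lesion still binds the probes, so this level checks nothing about the strain label. The helicase gene drh-1, whose product is needed for antiviral RNA interference, was read at 7.08 ± 0.16 in uninfected N2, 7.64 ± 0.41 in uninfected JU1580 and 7.48 ± 0.12 in uninfected rde-1. A second drh-1 probe set, dim on all arrays, read 3.82 ± 0.23 in uninfected N2 and 3.54 ± 0.08 in uninfected JU1580. The Dicer gene dcr-1 lay at 7.81 ± 0.35, 7.99 ± 0.55 and 8.47 ± 0.12 in the same order. None of these 3 genes passed the threshold in any of the 8 comparisons. The infection effects of drh-1 were 0.58 ± 0.16 (SE) in N2, -0.10 ± 0.19 in JU1580 and 0.17 ± 0.19 in rde-1.

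Arrays within a group differed in germline and tissue transcripts. The mean of the 20 oocyte and eggshell genes was 11.3 in N2 uninfected 1 and 10.2 to 10.6 in the other uninfected N2 arrays. It was 11.7 in JU1580 uninfected 1 and 10.6 and 10.9 in the other uninfected JU1580 arrays, and 9.69 in JU1580 infected 3 against 10.8 and 10.9 in the other infected ones. Neuronal genes ran the other way, with 8.32 in JU1580 infected 3 against 7.23 and 7.35. These shifts lie within groups and also move with infection in N2 and JU1580, so they are given below beside the gene groups they move with.

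**Figure D1:**
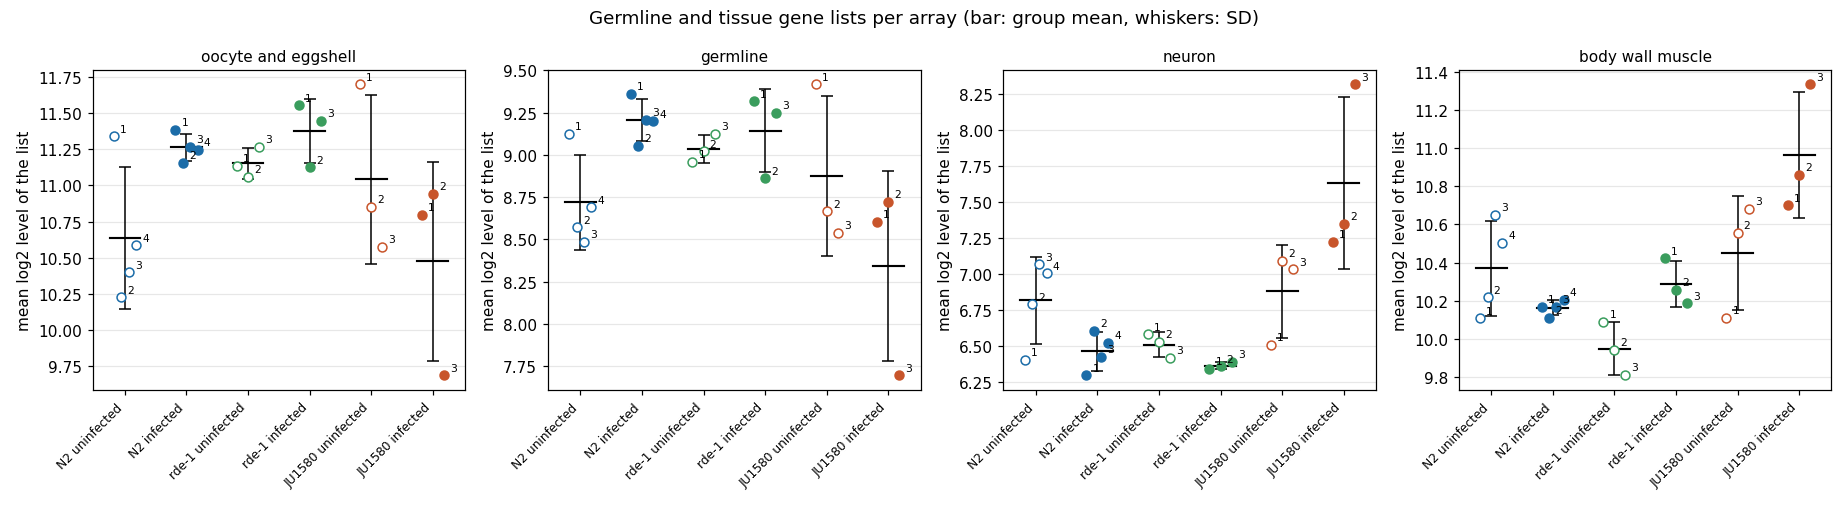
Mean log2 level of the oocyte and eggshell, germline, neuron and body wall muscle lists (vertical axes) in each array, by group (horizontal axis). Points are arrays with their replicate number, the bar is the group mean and the whiskers are the SD. JU1580 infected 3 is lowest for oocyte genes at 9.69 and highest for neuronal genes at 8.32.

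Infection of N2 was followed by rises in a small set of genes with low levels in uninfected animals. F26F2.4 rose by 4.69 ± 0.23 log2 units (SE, n = 4 and 4), from 3.30 ± 0.12 to 7.99 ± 0.48 (SD). ddn-1 rose by 3.98 ± 0.21, B0507.8 by 3.94 ± 0.15, and eol-1, which encodes a relative of the DXO family of RNA decapping enzymes, by 3.50 ± 0.25. The neighbours F26F2.5, F26F2.3 and F26F2.1 rose by 3.36 ± 0.17, 3.36 ± 0.25 and 2.89 ± 0.21. The genes C43D7.4, C49C8.2 and sdz-6 rose by 3.06 ± 0.16, 2.66 ± 0.25 and 2.43 ± 0.24.

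The pals genes encode proteins with a shared ALS2CR12-like domain, and several are known to respond to intracellular pathogens. Of 23 measured in N2, 9 rose and none fell, 14 and 0 adjusted over the list alone, with a list median of 0.52 ± 0.24 (SE of the median). pals-6 rose by 3.22 ± 0.29, pals-5 by 2.53 ± 0.20, pals-28 by 1.72 ± 0.19 and pals-11 by 1.64 ± 0.19. Of the 27 other genes of the intracellular infection response, 14 rose and none fell, and 18 rose and 1 fell adjusted over the list alone, with a median of 1.0 ± 0.38. Both lists passed camera, at adjusted p = 1.96e-16 and 4.55e-37, and passed again at adjusted p = 0.00406 and 0.000736 with an estimated correlation. Of 171 F-box A genes, which encode putative substrate receptors of ubiquitin ligases, fbxa-75 (1.42 ± 0.16) and fbxa-158 (1.09 ± 0.19) rose, the list median was -0.03, and camera gave adjusted p = 0.562.

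In N2 6 genes fell past the threshold, a number that rests on the arrays included: 679 probe sets were called lower without N2 uninfected 1, 0 to 3 without any other N2 array and 0 with the germline covariate, a setting chosen after the data were seen. The 6 were nlp-31, an antimicrobial neuropeptide-like gene (-1.62 ± 0.30), dod-24 (-1.59 ± 0.27), far-3, which encodes a fatty acid and retinol binding protein (-1.20 ± 0.23), F59B10.5 (-1.17 ± 0.22), F25D1.5 (-1.17 ± 0.21) and F52E1.14 (-0.50 ± 0.10). Among 70 lysozyme and antimicrobial peptide genes 1 fell, 18 fell adjusted over the list alone, and the median was -0.45 (camera adjusted p = 2.35e-12). That call was lost at adjusted p = 0.157 with an estimated correlation. The 24 genes of the bacterial infection response, among them irg and dod genes known to respond to bacterial pathogens in the intestine, had a median of -0.46 with 1 fall, and 1 rise and 9 falls adjusted over the list alone. Their camera adjusted p was 7.62e-06, with adjusted p = 0.131 with an estimated correlation.

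Oocyte genes lay higher in infected than in uninfected N2 by a median of 0.69 with no member called, and germline genes by 0.59 with 1 member called adjusted over the list alone. Camera adjusted p of 1.12e-08 and 2.77e-07 became adjusted p = 0.417 and 0.417 with an estimated correlation. The Argonaute list moved the same way (median 0.64, 0 calls, 9 rises adjusted over the list alone, camera adjusted p = 1.88e-09, adjusted p = 0.157 with an estimated correlation), as did antiviral RNA interference genes (median 0.33, 0 calls, 3 rises adjusted over the list alone, camera adjusted p = 3.32e-06, adjusted p = 0.315 with an estimated correlation). Neuronal genes had a median of -0.39 and body wall muscle genes of -0.20, with no member called. Their camera adjusted p were 0.00301 and 0.0147, and adjusted p = 0.575 and 0.601 with an estimated correlation.

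In N2, 37 probe sets passed limma's Benjamini-Hochberg threshold, 31 higher and 6 lower, and 32 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 3874. For all 18 named genes every infected array lay beyond every uninfected array, which tests nothing further, since these genes were named as the largest calls on the same arrays. The count rests on which arrays enter: it was 1465 without N2 uninfected 1, the array with the high oocyte genes (786 higher and 679 lower, 53.7% higher against 83.8%), 25 to 33 without any other N2 array, and 176 without JU1580 uninfected 1, which enters only through the shared spread. The genes that rose most are dim before infection, and with the dimmer 50% of probe sets left out 8 of the 37 were still tested and 1 was called.

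Infection of rde-1 animals was also followed by rises in genes that are dim in uninfected animals. F26F2.4 rose by 5.44 ± 0.27 (SE, n = 3 and 3), from 3.25 ± 0.10 to 8.69 ± 0.70 (SD), F26F2.3 by 5.27 ± 0.29, F26F2.1 by 4.81 ± 0.24, F26F2.5 by 3.56 ± 0.19, ddn-1 by 4.72 ± 0.25 and eol-1 by 4.45 ± 0.28. B0507.8 rose by 4.23 ± 0.18, C43D7.4 by 4.02 ± 0.19, C53A5.11 by 3.51 ± 0.41 and F07E5.9 by 3.53 ± 0.25. The gene trpl-5, named as a TRP channel relative, rose by 3.86 ± 0.15.

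Of the 23 pals genes 14 rose and none fell in rde-1, 17 rising and 1 falling adjusted over the list alone, with a median of 1.21 ± 0.29. pals-5 rose by 3.62 ± 0.23, pals-28 by 2.68 ± 0.21, pals-4 by 2.68 ± 0.23 and pals-29 by 2.34 ± 0.19. Of the 27 other response genes 18 rose and none fell, 21 rising and 1 falling adjusted over the list alone, and the median was 2.81 ± 0.47. Both passed camera at adjusted p = 7.62e-39 and 7.37e-65, and adjusted p = 4.46e-05 and 3.17e-05 with an estimated correlation. Among F-box A genes fbxa-158 (2.57 ± 0.22), fbxa-75 (2.06 ± 0.19) and fbxa-86 (1.56 ± 0.20) rose, while the list median was 0.00 and camera gave adjusted p = 0.461. Of 85 genes with MATH domains, 4 rose and none fell, with 7 rising and 2 falling adjusted over the list alone, and the list median was 0.05. They were math-17 (1.118 ± 0.13), math-5 (1.09 ± 0.17), math-15 (1.116 ± 0.21) and math-16 (0.98 ± 0.19), and the list's camera adjusted p of 0.0447 became adjusted p = 0.579 with an estimated correlation.

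The 8 genes that fell in rde-1 included fat-7, which encodes a stearoyl-CoA desaturase (-1.26 ± 0.26), far-3 (-1.32 ± 0.26), the sodium-proton exchanger gene nhx-6 (-1.16 ± 0.22) and the lipase-related lips-17 (-0.85 ± 0.14). The other 4 were F43H9.4 (-1.124 ± 0.23), F20G2.1 (-0.98 ± 0.19), crp-1 (-0.84 ± 0.17) and F52E1.14 (-0.52 ± 0.11). All 22 intestine marker genes had a negative change, with a median of -0.31 and no member called (camera adjusted p = 8.51e-06, adjusted p = 0.162 with an estimated correlation). The mean level of body wall muscle genes was 9.95 ± 0.14 (SD) in uninfected and 10.29 ± 0.12 in infected rde-1. That of lysozyme and antimicrobial peptide genes was 6.89 ± 0.03 and 6.60 ± 0.03. Of 15 fatty acid desaturation and elongation genes fat-7 fell, and the median was -0.37 (camera adjusted p = 2.46e-05, adjusted p = 0.162 with an estimated correlation). The 104 UGT and GST genes of detoxification had a median of -0.21 and the 73 cytochrome P450 genes of -0.13, with no member called in either. The lists had camera adjusted p of 8.27e-09 and 0.000415, and adjusted p = 0.0985 and 0.171 with an estimated correlation. The bacterial response list had no call, a median of -0.07, a mean of 0.12 and camera adjusted p = 0.797, so its median and mean differed in sign. In all, 85 probe sets passed in rde-1, 76 higher and 9 lower, 64 of them by at least 2-fold, and 1935 had an unadjusted p under 0.05. All 20 named genes, picked by the same rule, showed their direction in every array. Leaving out 1 rde-1 array at a time gave 61 to 78 calls. The lower calls among them numbered 1 without rde-1 uninfected 1, 1 without rde-1 uninfected 2 and 3 to 9 without any other, and 41 when only the 6 rde-1 arrays were fitted. Of all calls, 7 remained with the dimmer 50% of probe sets left out, where 17 of the 85 were tested.

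**Figure D2:**
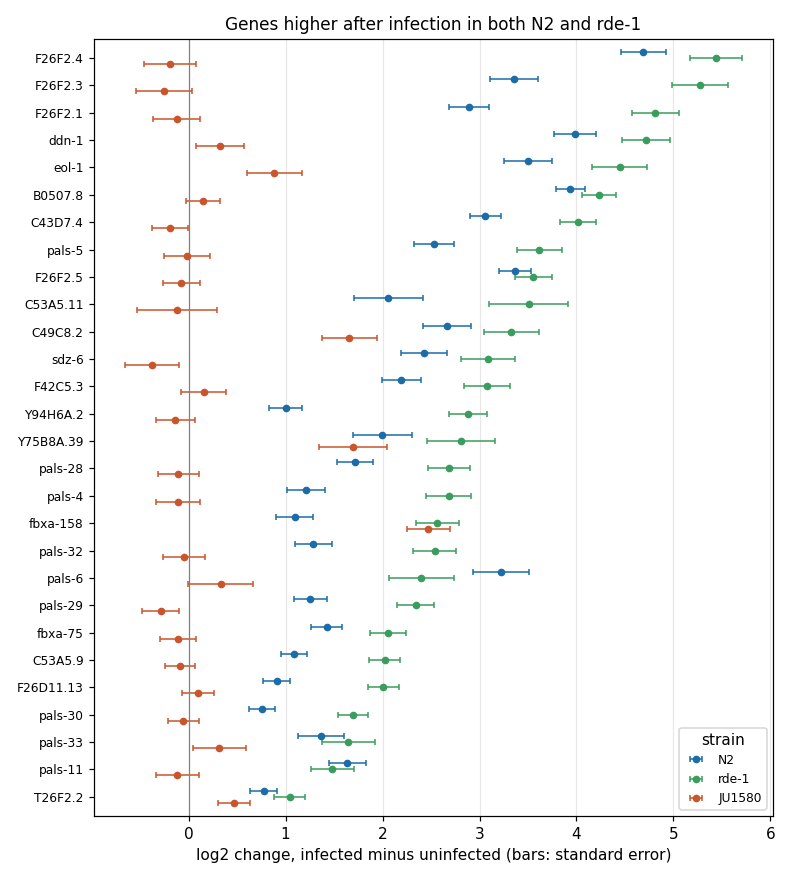
Log2 change after infection (horizontal axis) with its SE for the 28 genes called higher in both N2 and rde-1 (vertical axis), in N2 (n = 4 and 4), rde-1 (n = 3 and 3) and JU1580 (n = 3 and 3). The JU1580 points lie around 0 for most genes, with a median of -0.07, while C49C8.2, Y75B8A.39 and fbxa-158 rise there too.

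Infection of JU1580 was followed by rises in genes led by T05A7.3, B0024.4 and B0348.2. T05A7.3 rose by 4.80 ± 0.29 (SE, n = 3 and 3), from 4.12 ± 0.21 to 8.92 ± 0.68 (SD), B0024.4 by 4.61 ± 0.41, B0348.2 by 4.51 ± 0.30 and F55G11.3 by 4.45 ± 0.18. The C-type lectin genes clec-174 and clec-140 rose by 4.32 ± 0.21 and 3.35 ± 0.30, and lys-3, a lysozyme gene, by 3.36 ± 0.46. cld-9 rose by 3.66 ± 0.28, Y47H10A.5 by 3.18 ± 0.30 and warf-1, a gene of the ARF family of small GTPases, by 3.05 ± 0.35.

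Of the 24 bacterial infection response genes 14 rose in JU1580 and none fell, 18 and 0 adjusted over the list alone, and the median was 1.22 ± 0.25. irg-6 rose by 3.30 ± 0.18, K08D8.4 by 3.104 ± 0.38, dod-22 by 2.86 ± 0.36 and C17H12.8 by 2.54 ± 0.16. The mean level of the list was 7.58 ± 0.30 (SD) in uninfected and 8.90 ± 0.10 in infected JU1580, beside 8.06 ± 0.10 in uninfected N2. Camera gave adjusted p = 3.82e-20 and, with an estimated correlation, adjusted p = 0.00165, the single list of the 28 that held in this comparison. Without JU1580 infected 3 the median was 0.97 ± 0.29 and 13 members were called, and with the germline covariate 11 were called.

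Of 220 C-type lectins 10 rose and none fell in JU1580 (12 and 5 adjusted over the list alone), with a median of -0.17 and camera adjusted p = 0.0967. In the lysozyme and antimicrobial list spp-27, a saposin-like gene (2.90 ± 0.22), lys-3 and lys-1 (0.59 ± 0.11) rose, lys-4 (-0.85 ± 0.18) and ilys-2 fell (3 and 5 adjusted over the list alone), and the median was -0.07 with a mean of 0.02 and camera adjusted p = 0.802. Of 171 F-box A genes 16 rose and none fell (19 and 3 adjusted over the list alone), led by fbxa-158 (2.47 ± 0.22) and fbxa-163 (1.16 ± 0.15), while the median was -0.09, the mean 0.04 and camera adjusted p = 0.408. Of 139 F-box B and C genes fbxc-58 rose (2.75 ± 0.34), fbxb-2 fell (-0.52 ± 0.12) and the median was -0.19 (camera adjusted p = 3.73e-05, adjusted p = 0.524 with an estimated correlation).

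The pals genes had a median change of -0.05 and a mean of 0.06 in JU1580, with camera adjusted p = 0.582, and pals-23 alone passed (1.68 ± 0.23). Of the other 27 intracellular response genes 4 rose and none fell, 5 and 0 adjusted over the list alone, with a median of 0.03. They were cul-6 (1.59 ± 0.26) and skr-3 (1.16 ± 0.23), which encode a cullin and a Skp1 relative of ubiquitin ligase complexes, C49C8.2 (1.66 ± 0.29) and Y75B8A.39 (1.69 ± 0.35). The list's camera adjusted p of 0.0204 became adjusted p = 0.524 with an estimated correlation.

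Genes that fell in JU1580 included fat-7 (-1.31 ± 0.26), the aspartic protease gene asp-13 (-1.09 ± 0.19), the dehydrogenase gene dhs-26 (-1.15 ± 0.27) and the cuticle collagen genes col-81, col-137 and col-63 (-1.19 ± 0.28, -1.05 ± 0.25 and -1.03 ± 0.27). Others were D1086.3 (-1.95 ± 0.50), Y51H7C.1 (-1.33 ± 0.32), Y51H7C.13 (-0.99 ± 0.20), lsy-27 (-1.04 ± 0.22), W04A4.2 (-0.97 ± 0.21) and the ephrin gene efn-3 (-0.92 ± 0.24). Of 164 collagen genes 2 rose and 4 fell, 7 and 35 adjusted over the list alone, and the median was -0.27 (camera adjusted p = 0.000127, adjusted p = 0.524 with an estimated correlation). Of 20 molting genes 4 rose and none fell, ptr-14 (0.77 ± 0.18), nas-37 (0.81 ± 0.19), nhr-25 (1.05 ± 0.26) and fbn-1 (0.91 ± 0.23), with a median of 0.48 (camera adjusted p = 0.000127, adjusted p = 0.494 with an estimated correlation).

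Tissue and stage lists passed camera in JU1580 as well. Neuronal genes had a median of 0.91, with mec-12 called (1.27 ± 0.31) and 13 rises adjusted over the list alone, and body wall muscle genes of 0.40, with none called and 3 adjusted over the list alone. In camera they had adjusted p = 1.24e-07 and 3.17e-06, and adjusted p = 0.494 for both with an estimated correlation. Oocyte, germline and sperm genes had medians of -0.65, -0.50 and -0.26 with no member called. Their camera adjusted p of 0.00299, 0.000323 and 0.00017 became adjusted p = 0.65, 0.524 and 0.524 with an estimated correlation. The intestine list had 2 rises, eps-8 (0.87 ± 0.20) and ifb-2 (0.86 ± 0.20), a median of 0.22 and camera adjusted p = 0.0576. The 5 vitellogenins, yolk protein genes, had a median of -0.26 with none called (camera adjusted p = 0.035, adjusted p = 0.524 with an estimated correlation). The 62 ribosomal protein genes had a median of 0.10 (camera adjusted p = 4.77e-05, adjusted p = 0.494 with an estimated correlation), and early embryo genes of -0.30 with camera adjusted p = 0.0714.

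In JU1580, 630 probe sets passed, 543 higher and 87 lower, 316 of them by at least 2-fold, and 5639 had an unadjusted p under 0.05. With arrays centred on their medians the split was 487 higher and 299 lower, a share of 62.0% higher against 86.2%. The 24 named genes, again the largest calls on these arrays, showed their direction in every array. The count was 208 without JU1580 uninfected 1, 230 without JU1580 infected 3, 2522 without JU1580 infected 1 and 416 without rde-1 uninfected 1, and 32 when only the 6 JU1580 arrays were fitted. Lower calls numbered 28 without JU1580 uninfected 1, 5 without JU1580 infected 3, 884 without JU1580 infected 1 and 0 with the JU1580 arrays alone. With the germline covariate 236 of the 630 kept their call. The SEs and p-values given for JU1580 use the spread pooled over all groups, which may be narrower than that of the JU1580 arrays.

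**Figure D3:**
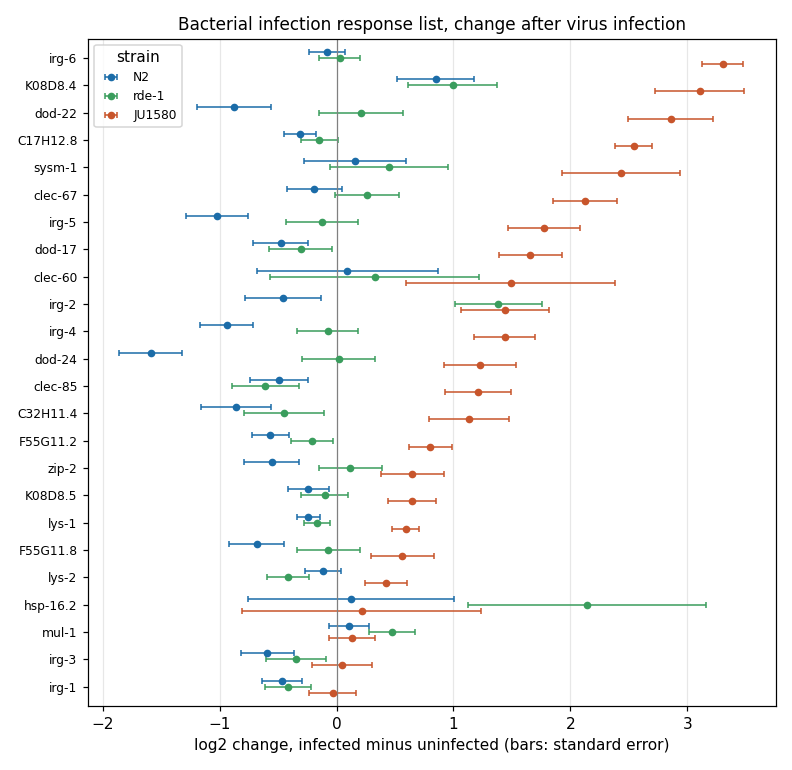
Log2 change after infection (horizontal axis) with its SE for the 24 genes of the bacterial infection response list (vertical axis), in N2 (n = 4 and 4), rde-1 (n = 3 and 3) and JU1580 (n = 3 and 3). The JU1580 points lie to the right of 0 for 23 of the 24 genes, with a median of 1.22.

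Nearly all probe sets that rose in N2 also rose in rde-1, while most of those that rose in rde-1 were not called in N2. Of 31 probe sets higher in N2, 30 were among the 76 higher in rde-1, where independent lists of these sizes share 0.104 (one-sided Fisher's exact test, p = 2.76e-76, 3.31e-75 adjusted over 12 tests). These made 28 genes, 22 of them in the pals or intracellular response lists, with a median change of 2.03 ± 0.26 in N2, 2.85 ± 0.28 in rde-1 and -0.07 ± 0.16 in JU1580 (SE of the median). The genes were picked for their calls in N2 and rde-1 on these arrays, which raises the medians of those 2 strains. In JU1580, C49C8.2, Y75B8A.39 and fbxa-158 of the 28 rose. JU1580 and rde-1 shared 10 higher probe sets against 1.83 by chance (adjusted p = 5.54e-05), and N2 and JU1580 shared 3 against 0.747 (adjusted p = 0.0758). Of the 6 probe sets lower in N2, 2 were higher in JU1580 against 0.144 by chance (adjusted p = 0.0244), those of dod-24 and F52E1.14, and 2 were lower in rde-1 against 0.00239 (adjusted p = 1.27e-05), those of far-3 and F52E1.14, both pairs being chosen after their values were seen. Across probe sets, which are not independent replicates, the changes of N2 and rde-1 correlated at r = 0.49 (Spearman 0.42), above the highest of 100 regroupings at 0.46. The values were -0.39 for N2 with JU1580 and -0.13 for JU1580 with rde-1, and regrouped arrays gave values as large in 31 and 36 of 100.

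The differences between the infection effects were tested directly. The effect in JU1580 lay below that in N2 for F26F2.4 (-4.88 ± 0.36, SE), B0507.8 (-3.79 ± 0.23), ddn-1 (-3.66 ± 0.33), F26F2.3 (-3.61 ± 0.38), F26F2.5 (-3.44 ± 0.25), C43D7.4 (-3.25 ± 0.25), F26F2.1 (-3.02 ± 0.32) and pals-6 (-2.89 ± 0.44). It lay above that in N2 for clec-174 (4.504 ± 0.28), F55G11.3 (4.39 ± 0.24), B0348.2 (4.31 ± 0.40), T05A7.3 (3.98 ± 0.38), dod-22 (3.73 ± 0.48), cld-9 (3.59 ± 0.37), irg-6 (3.38 ± 0.23) and warf-1 (3.27 ± 0.46). All 16 passed, the largest adjusted p being that of pals-6 at 0.00169. Of the 28 shared genes, 24 differed between JU1580 and N2 and 23 between JU1580 and rde-1. With the germline covariate, a setting chosen after the data were seen, these were 15 and 23, and with 1 array left out 18 to 24 and 21 to 23. The 28 genes were picked for their calls in N2 and rde-1 on the same arrays. That choice favours such differences, so the counts are no independent support.

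The bacterial response list stood above its N2 effect in JU1580, with all 24 genes positive, 14 called, 19 adjusted over the list alone and a median difference of 1.80 ± 0.26 (SE). Camera gave adjusted p = 1.67e-18, and adjusted p = 0.00252 with an estimated correlation. Of 23 pals genes 1 lay above and 10 below, 2 and 13 adjusted over the list alone, with a median of -0.56, and of the 27 other response genes 1 and 14, 3 and 15 adjusted over the list alone, with a median of -1.01. The camera adjusted p of 1.15e-05 and 1.39e-09 became adjusted p = 0.188 and 0.122 with an estimated correlation. Neuronal genes differed by a median of 1.41 with 6 members called, mec-12 among them, and oocyte genes by -1.30 with none called and 15 lower adjusted over the list alone. Camera gave adjusted p = 1.74e-07 and 7.96e-07, and adjusted p = 0.358 and 0.403 with an estimated correlation. In this comparison 912 probe sets passed, 662 higher and 250 lower, 711 of them by at least 2-fold, with 6591 at an unadjusted p under 0.05. With centred arrays the split was 528 and 473, 52.7% higher against 72.6%, and with quantile scaling 476 and 255, 65.1%. With the germline covariate 91 were called, 73 higher and 18 lower, 87 of them among the 912, and with only the compared arrays 151, 123 higher and 28 lower. Of the 14 arrays compared, 13 moved the count by over 1.5 times when left out: it was 3868 without N2 uninfected 1 (2158 higher and 1710 lower, 55.8% higher), 3356 without JU1580 uninfected 3, 3169 without JU1580 infected 1, 2947 without JU1580 infected 2 and 178 to 376 without any of 9 others. Leaving out an rde-1 array, which enters only through the shared spread, gave 964 for rde-1 infected 2 and 400 to 568 for the 5 others.

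Set against rde-1, the effect in JU1580 lay above for F55G11.3 (4.23 ± 0.25, SE), clec-174 (4.10 ± 0.30), cld-9 (3.87 ± 0.40), B0024.4 (3.65 ± 0.59), B0348.2 (3.64 ± 0.43), warf-1 (3.43 ± 0.49), irg-6 (3.27 ± 0.25) and valv-1 (3.20 ± 0.45). It lay below for F26F2.4 (-5.63 ± 0.38), F26F2.3 (-5.53 ± 0.40), F26F2.1 (-4.94 ± 0.34), ddn-1 (-4.397 ± 0.35), C43D7.4 (-4.21 ± 0.26), trpl-5 (-4.11 ± 0.21), B0507.8 (-4.09 ± 0.25) and F07E5.9 (-3.66 ± 0.36). The pals list (median -1.02, 1 above and 13 below, 1 and 18 adjusted over the list alone), the other intracellular response genes (median -1.67, 1 and 14, 1 and 17) and the bacterial response list (median 1.19, 8 and 0, 16 and 0) all passed camera. The adjusted p were 1.35e-13, 8.99e-20 and 3.02e-14, and adjusted p = 0.00668 for each with an estimated correlation. Here 234 probe sets passed, 149 higher and 85 lower, 202 of them by at least 2-fold, with 4868 at an unadjusted p under 0.05. With only the compared arrays fitted 92 passed, 50 higher and 42 lower, and with a replicate block 464, 334 higher and 130 lower. The count was 102 without rde-1 uninfected 1, 109 without rde-1 uninfected 2, 142 without JU1580 uninfected 1 and also without rde-1 infected 2, 423 without JU1580 uninfected 3 and 612 without JU1580 infected 1, and 128 of the 234 kept their call with the germline covariate.

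Between rde-1 and N2 the effect of infection was larger in rde-1 for 7 genes. They were trpl-5 (3.26 ± 0.20, SE), F07E5.9 (2.87 ± 0.33), M01G12.7 (2.13 ± 0.31), F26F2.1 (1.92 ± 0.32), Y94H6A.2 (1.88 ± 0.26), droe-8 (1.78 ± 0.26) and F15H10.6 (1.67 ± 0.17). The pals list lay higher by a median of 0.38 ± 0.14 with no member called and 9 adjusted over the list alone, and the other response genes by 0.67 ± 0.19 with 3 called and 7 adjusted over the list alone. Camera gave adjusted p = 6.25e-11 and 1.64e-14, and adjusted p = 0.0266 for both with an estimated correlation. At an unadjusted p under 0.05 there were 1027 probe sets. Of 100 regroupings of the arrays, 5 gave at least 7 calls, counting the true one. The regrouping with the most calls, 19, kept the true rde-1 groups and so the infection effect of that strain. The regroupings therefore cannot decide whether the count of 7 exceeds chance. That count was 13 without N2 infected 2 and 11 without rde-1 infected 1.

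**Figure D4:**
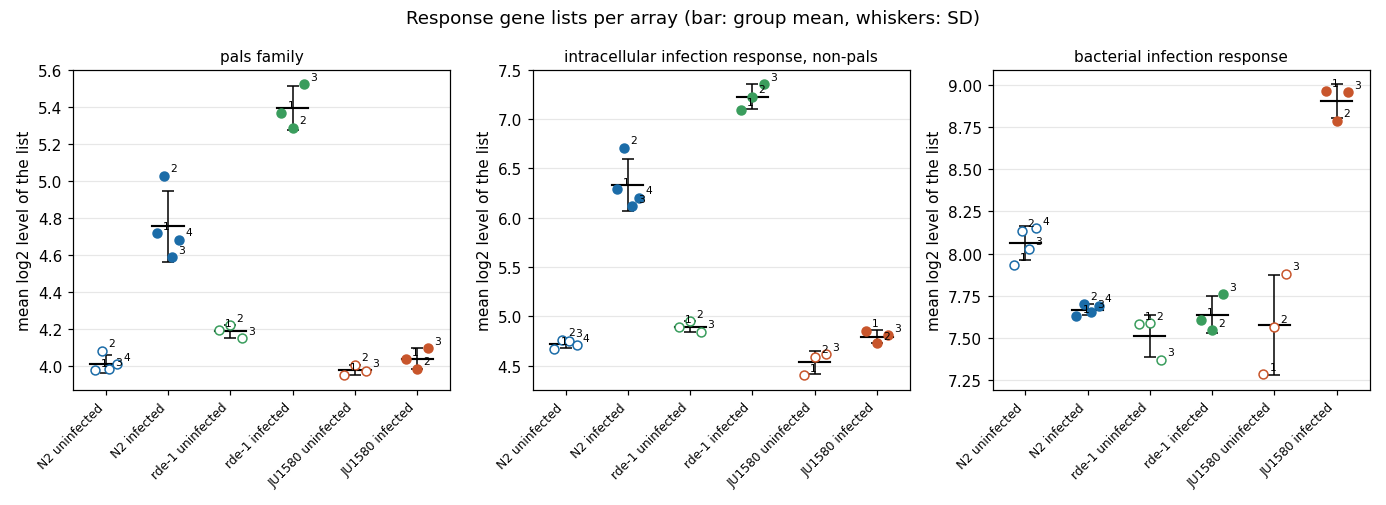
Mean log2 level (vertical axes) of the pals list, the other intracellular response genes and the bacterial response list in each array, by group (horizontal axis). Points are arrays with their replicate number, the bar is the group mean and the whiskers are the SD. The pals list goes from 4.01 to 4.76 in N2 and from 4.19 to 5.40 in rde-1, and the bacterial list from 7.58 to 8.90 in JU1580.

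The other lists had few members past the threshold after infection. Histone genes had a median of -0.12 in N2 (camera adjusted p = 0.0303, adjusted p = 0.581 with an estimated correlation) and of 0.10 in rde-1, where the linker histone gene his-24 rose by 1.05 ± 0.22 (camera adjusted p = 0.0255, adjusted p = 0.6 with an estimated correlation). The 15 mitochondrial and ER stress genes had medians of 0.31, 0.22 and 0.25 in N2, JU1580 and rde-1 with no member called. Their camera adjusted p of 0.0049, 0.0064 and 0.0148 became adjusted p = 0.468, 0.524 and 0.579 with an estimated correlation. The 8 heat shock genes had medians of -0.23, 0.40 and 0.13, and the 15 targets of ERGO-1 small RNAs of -0.09, 0.01 and 0.05, with no member called and no camera call in either list. The mean level of the heat shock list was 6.83 ± 0.09 (SD) in uninfected and 7.56 ± 0.18 in infected rde-1, a mean change of 0.72. Its median change of 0.13 there had an SE over genes of 0.59 (camera adjusted p = 0.332), and uninfected N2 arrays ranged from 6.65 to 8.88. With an estimated correlation, of the lists past camera the pals and the other intracellular response lists held in N2, in rde-1, in rde-1 against N2 and in JU1580 against rde-1, and the bacterial list in JU1580 and in JU1580 against each of the other strains. In the comparisons of uninfected strains no list held. Of 224 pairs of a list and a comparison, median and mean differed in sign in 23.

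Uninfected JU1580 and N2 differed at many genes before any infection. Y39B6A.21 was higher in JU1580 by 4.83 ± 0.43 (SE, n = 3 and 4), Y82E9BL.9 by 4.06 ± 0.20, F12E12.6 by 3.14 ± 0.29, C06C3.5 by 3.01 ± 0.33, C36C5.4 by 2.72 ± 0.29 and exh-1 by 2.65 ± 0.18. The L-2-hydroxyglutarate dehydrogenase gene lhgd-1 was higher by 2.74 ± 0.21 and the Skp1-related gene skr-11 by 2.65 ± 0.24. Lower in JU1580 were Y14H12A.1 (-5.04 ± 0.24), F43C11.3 (-4.79 ± 0.20), F54E2.1 (-4.62 ± 0.23), F42A9.6 (-4.53 ± 0.18), C13G5.2 (-3.72 ± 0.17) and the lysozyme gene lys-7 (-3.51 ± 0.42).

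Of 171 F-box A genes 4 were higher and 25 lower in uninfected JU1580, 5 and 27 adjusted over the list alone, with fbxa-210 at -4.47 ± 0.16 and fbxa-107 at -3.61 ± 0.14. The list's median was 0.01 and its mean -0.21, opposite in sign, and camera gave adjusted p = 0.00673 for a lower list, with adjusted p = 0.624 with an estimated correlation. Of 68 sperm genes 23 were lower and none higher (35 and 0 adjusted over the list alone), among them msp-33 (-1.15 ± 0.23) and ssp-31 (-0.92 ± 0.18), with a median of -0.56 (camera adjusted p = 6.45e-15, adjusted p = 0.534 with an estimated correlation). Of the bacterial response genes 8 were lower and none higher (12 and 0 adjusted over the list alone), among them irg-4 (-1.59 ± 0.25) and C17H12.8 (-1.86 ± 0.15), with a median of -0.48 (camera adjusted p = 1.55e-06, adjusted p = 0.201 with an estimated correlation). Of 220 C-type lectins 12 were lower and none higher (13 and 0 adjusted over the list alone), among them clec-49 (-3.13 ± 0.21), with a median of 0.00 and camera adjusted p = 0.257. The transcription factor genes atfs-1 (2.0 ± 0.21) and xbp-1 (0.62 ± 0.13), known from mitochondrial and ER stress, and the choline kinase gene ckb-2 (1.06 ± 0.20) were higher (list median 0.32, camera adjusted p = 8.28e-05, adjusted p = 0.534 with an estimated correlation). In the pals list pals-23 was at -1.41 ± 0.22 and pals-6 at 1.28 ± 0.31, 1 lower and 1 higher gene past the threshold.

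In this comparison 715 probe sets passed, 171 higher and 544 lower, 341 of them by at least 2-fold, with 3195 at an unadjusted p under 0.05. The 16 named genes, chosen as the largest of these calls, showed their direction in every array. Leaving out JU1580 uninfected 2 gave 388, JU1580 uninfected 1 397 and JU1580 uninfected 3 1083. With only the compared arrays fitted 191 were called, 45 higher and 146 lower. Of 35 splits of these arrays 2 gave as many calls, counting the true one. The other, at 1883, put N2 uninfected 1 with JU1580 uninfected 1 and 2. N2 uninfected 1 and JU1580 uninfected 1 had the highest oocyte levels of their groups, so that split does not stand for chance alone. The probes were designed on the N2 genome, and sequence differences in a wild isolate lower a probe's signal without any change in the transcript.

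Uninfected rde-1 and N2 differed at fewer genes. Y47H10A.5 was higher in rde-1 by 3.77 ± 0.28 (SE, n = 3 and 4), B0024.4 by 2.82 ± 0.39, B0348.2 by 2.15 ± 0.28, Y39D8A.1 by 2.28 ± 0.29 and pals-6 by 2.22 ± 0.31. Of the 85 MATH domain genes 9 were higher and none lower, 15 and 0 adjusted over the list alone, among them math-18 (2.31 ± 0.30), math-20 (2.15 ± 0.25) and math-37 (2.14 ± 0.26), with a median of 0.07 (camera adjusted p = 1.09e-06, adjusted p = 0.15 with an estimated correlation). Lower were sysm-1 (-2.57 ± 0.47) and dod-24 (-2.27 ± 0.29) of the bacterial response list, ctsa-2, a cathepsin A relative (-2.19 ± 0.21), slc-17.1 (-1.69 ± 0.21), sshk-1 (-1.63 ± 0.31), Y40H7A.10 (-1.35 ± 0.29), T10B5.7 (-1.27 ± 0.22) and Y110A2AL.3 (-1.27 ± 0.21).

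Of the bacterial response genes 4 were lower in uninfected rde-1 and none higher, 7 lower and 2 higher adjusted over the list alone, with a median of -0.37 (camera adjusted p = 9.27e-06, adjusted p = 0.15 with an estimated correlation). Histone genes had a median of -0.33 with none called and 10 lower adjusted over the list alone (camera adjusted p = 4.47e-09, adjusted p = 0.15 with an estimated correlation). Oocyte genes lay higher by a median of 0.45 and body wall muscle genes had a median of -0.43, with no member called. Camera gave adjusted p = 1.09e-06 and 2.95e-06, and adjusted p = 0.515 and 0.434 with an estimated correlation. The yolk protein gene vit-2 was lower (-0.79 ± 0.17, list median -0.16, camera adjusted p = 0.0377, adjusted p = 0.515 with an estimated correlation). In all, 123 probe sets passed, 91 higher and 32 lower, 86 of them by at least 2-fold, with 2521 at an unadjusted p under 0.05. The 16 named genes, chosen likewise, showed their direction in every array. The count was 56 and 64 without rde-1 uninfected 1 and 2, and 326 without N2 uninfected 1. Lower calls numbered 9 and 12 without rde-1 uninfected 1 and 2. Without N2 uninfected 1 the split was 169 higher and 157 lower, 51.8% higher against 74.0%.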

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

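The differences between the strains' infection effects and 3 single values that lie far from the others of their group were marked for a closer look. The array splits, the RNA degradation test and the other-strain test were fixed before their results were seen. The tests on the shared response, on the bacterial response list and on germ cell content were chosen after the result they address was seen.

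Between JU1580 and N2 the effect of infection differed at 912 probe sets, of which 87 kept their call with the germline covariate. It was above N2 in JU1580 for clec-174 (4.504), F55G11.3 (4.39), B0348.2 (4.31), T05A7.3 (3.98), dod-22 (3.73), cld-9 (3.59), irg-6 (3.38), warf-1 (3.27) and the bacterial response list (1.80). It was below N2 for F26F2.4 (-4.88), B0507.8 (-3.79), ddn-1 (-3.66), F26F2.3 (-3.61), F26F2.5 (-3.44), C43D7.4 (-3.25), F26F2.1 (-3.02) and pals-6 (-2.89).

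Between JU1580 and rde-1 it differed at 234 probe sets, of which 128 kept their call with that covariate. It was above rde-1 for F55G11.3 (4.23), clec-174 (4.10), cld-9 (3.87), B0024.4 (3.65), B0348.2 (3.64), warf-1 (3.43), irg-6 (3.27), valv-1 (3.20) and the bacterial response list (1.19). It was below rde-1 for F26F2.4 (-5.63), F26F2.3 (-5.53), F26F2.1 (-4.94), ddn-1 (-4.397), C43D7.4 (-4.21), trpl-5 (-4.11), B0507.8 (-4.09), F07E5.9 (-3.66), the pals list (-1.02) and the other intracellular response genes (-1.67). Between rde-1 and N2 it differed at 7 probe sets, those of trpl-5 (3.26), F07E5.9 (2.87), M01G12.7 (2.13), F26F2.1 (1.92), Y94H6A.2 (1.88), droe-8 (1.78) and F15H10.6 (1.67), and for the pals list (0.38) and the other intracellular response genes (0.67).

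Of 98 sets of replicate values tested, all in the N2 groups of 4 arrays, 3 held an array far from the others, where chance marks about 1 in 20. The groups of 3 arrays, JU1580 infected among them, are too small for this rule and were not tested by it. The Argonaute list read 7.29 in N2 uninfected 1 against 6.83 in the nearest array, the F-box B and C list 4.35 in N2 uninfected 2 against 4.33, and the rde-1 gene 8.53 in N2 uninfected 3 against 8.73.

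Arrays were also split into groups of the true sizes without regard to label, counting the true split. For infection in N2, 1 of 35 splits gave as many calls, 37 against at most 1 elsewhere. For infection in JU1580 and in rde-1 it was 1 of 10 each, 630 against 6 and 85 against 0, and 10 splits are too few to give a share below 0.05. For the strain differences it was 3 of 100 for JU1580 against N2, where another split gave 3186, 1 of 100 for JU1580 against rde-1 (highest other 181), and 5 of 100 for rde-1 against N2 (highest other 19). For uninfected JU1580 against N2 and uninfected rde-1 against N2 it was 2 of 35 each, with other splits reaching 1883 and 611. The splits therefore do not exclude chance for the last 3, nor for infection in JU1580 and in rde-1. They do not stand for chance alone, though. Those at 3186, 181 and 19 calls kept the true groups of N2, JU1580 and rde-1 in turn. That at 1883 put N2 uninfected 1 with JU1580 uninfected 1 and 2, and that at 611 put it with the uninfected rde-1 arrays. N2 uninfected 1 and JU1580 uninfected 1 had the highest oocyte levels of their groups. The splits thus cannot show that these counts arise by chance either. For JU1580 against N2 the share lies below 0.05, but the true count of 912 was not the highest.

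The first pattern is that the 28 shared response genes have a median change near 0 in JU1580. Sequence variants under the probes could hide a rise, but 0 of these genes lie above the array median in uninfected N2 and 5 were needed, so this could not be decided. The outlying array JU1580 infected 3 is argued against, since the median was -0.048 ± 0.17 (SE over genes) without it. A lower drh-1 transcript is argued against by a difference of 0.56 ± 0.17 between uninfected JU1580 and N2. That probe set is not a plain _at one, so it can read related transcripts, and it may still read a truncated transcript. A second, plain drh-1 probe set near the floor differed by -0.28 ± 0.13. Transcript levels do not test whether the DRH-1 protein works, so a loss of its function stays open. A weaker or earlier stage of infection in JU1580 may also give this and was not tested.

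The second pattern is the rise of the bacterial response genes in JU1580. A lower share of germline RNA could raise all somatic genes. As the whole cause it is argued against by the intestine and muscle lists, whose medians lay 1.0 and 0.82 below the bacterial list median (combined SE 0.28 and 0.27). The neuron list median lay 0.31 below it (combined SE 0.29), a margin too thin to decide. These SEs are over genes and leave out the spread between arrays. With the germline covariate the bacterial list median was 0.90, while the oocyte median went to 0.0285. Camera at the preset correlation gave the bacterial list adjusted p = 1.81e-23 there, and an estimated correlation was not tried with the covariate. JU1580 infected 3 does not account for the rise, with a list median of 0.97 ± 0.29 (SE over genes) without that array. A low level in uninfected JU1580 does not account for all of it, since infected JU1580 lay a median of 0.73 ± 0.29 (SE over genes) above uninfected N2. A bacterial contaminant of a virus preparation shared by the strains and acting alike in them is argued against by list medians of -0.46 in N2 and -0.0722 in rde-1, while one of the JU1580 cultures or of a separate preparation, or one that only JU1580 answers, could also raise these genes and was not tested.

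The third pattern is the position of JU1580 infected 3. RNA degradation as the main cause is argued against by a 3' minus 5' control difference of 1.19, inside the range of the other arrays, and N2 uninfected 2, at 1.46, had a median r of 0.977 with other arrays against 0.916 for this array. Its difference is the highest in JU1580, where the other arrays lie between 0.900 and 1.04, so a part played by degradation stays open. Another strain is argued against by a distance margin of 0.71 in favour of JU1580, a partly circular test because the marker probe sets were called on uninfected arrays of the same series. Fewer oocytes and germ cells fit, with a combined list level of -1.36 relative to the median of the other arrays, and younger animals or fewer gravid animals may lie behind it.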

How the results depend on the processing

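Tests with the germline covariate and with JU1580 infected 3 and rde-1 infected 2 left out together were chosen after the data were seen, and so was the rule that an uncalled value has no direction to reverse. Over named genes and lists 6542 alternative values stayed the same, 1200 became weaker, 9 stronger and 6 reversed, and over the main results 160 stayed the same, 78 moved by over 1.5 times and 4 became weaker. For rde-1, drh-1 and dcr-1, called nowhere in the main results, 22 of 276 alternatives changed sign and 9 were called. Counts of calls depend strongly on which arrays estimate the spread, while all 28 shared response genes kept their calls in rde-1 with any array left out. In N2 22 to 28 of them did, and with only the compared arrays fitted 20 in N2 and 27 in rde-1, and with the dimmer 50% of probe sets left out 1 in each. Except where stated, the cause was not tested.

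With only the compared arrays fitted, calls were 32 in JU1580, 151 for JU1580 against N2, 11 for rde-1 against N2, 92 for JU1580 against rde-1 and 191 for uninfected JU1580 against N2. With the dimmer 50% of probe sets left out they were 1 in N2, 347 in JU1580, 7 in rde-1, 1599 for JU1580 against N2, 0 for rde-1 against N2 and 103 for JU1580 against rde-1. That filter removes calls by construction, leaving 8 of the 37 in N2, 17 of the 85 in rde-1 and 0 of the 7 for rde-1 against N2 still tested, and of the 8 and 17 it kept 1 and 7, the cause of those further losses not being tested. With the dimmest 25% left out they were 47 in rde-1, 1536 for JU1580 against N2 and 4 for rde-1 against N2. With limma's array weights, whose fit warned of no convergence and gave weights of 0.0384 to 6.89, they were 5659 in N2, 4841 in JU1580, 5506 for JU1580 against N2, 25 for rde-1 against N2, 984 for JU1580 against rde-1, 6068 for uninfected JU1580 and 5025 for uninfected rde-1. With probe sets of a single transcript only they were 402 in JU1580, 594 for JU1580 against N2, 417 for uninfected JU1580 and 70 for uninfected rde-1, and with a 2-fold threshold 316 in JU1580 and 341 for uninfected JU1580. With JU1580 infected 3 and rde-1 infected 2 left out they were 58 in N2, 255 in JU1580, 350 for JU1580 against N2, 11 for rde-1 against N2, 150 for JU1580 against rde-1, 1102 for uninfected JU1580 and 210 for uninfected rde-1, where the arrays act only through the shared spread. With the germline covariate they were 284 in JU1580, 91 for JU1580 against N2, 147 for JU1580 against rde-1 and 1244 for uninfected JU1580.

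Whether replicate numbers pair samples was not settled, and no pairing was used in the main fit. In deviations from group means, infected and uninfected arrays of the same number often did not correlate best with each other. The correlation was 0.43 for JU1580 number 3 and 0.30 for N2 number 1, but -0.32 for JU1580 number 2 and -0.13 for rde-1 number 2. With a replicate block calls were 1212 in JU1580, 3395 for JU1580 against N2, 4 for rde-1 against N2 and 464 for JU1580 against rde-1, and with a replicate block across strains 2482 for JU1580 against N2.

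Leaving out 1 array at a time gave 25 to 1465 calls in N2 (1465 without N2 uninfected 1), 208 to 2522 in JU1580 (208 without JU1580 uninfected 1, 230 without JU1580 infected 3, 2522 without JU1580 infected 1) and 178 to 3868 for JU1580 against N2. In that comparison the values were 3868 without N2 uninfected 1, 3356 without JU1580 uninfected 3, 3169 and 2947 without JU1580 infected 1 and 2, 276, 241 and 240 without N2 uninfected 2 to 4, 195, 376, 316 and 317 without N2 infected 1 to 4, 178 without JU1580 uninfected 1 and 265 without JU1580 infected 3. Without an rde-1 array, which enters only through the shared spread, they were 400, 445 and 428 (uninfected 1 to 3) and 568, 964 and 438 (infected 1 to 3). The range was 5 to 13 for rde-1 against N2 (13 without N2 infected 2, 11 without rde-1 infected 1), 102 to 612 for JU1580 against rde-1 (102 and 109 without rde-1 uninfected 1 and 2, 142 without JU1580 uninfected 1 or rde-1 infected 2, 423 without JU1580 uninfected 3, 612 without JU1580 infected 1), 388 to 1083 for uninfected JU1580 (388, 397 and 1083 without JU1580 uninfected 2, 1 and 3) and 56 to 326 for uninfected rde-1 (56 and 64 without rde-1 uninfected 1 and 2, 326 without N2 uninfected 1).

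The bacterial list in N2 (median -0.46) had adjusted p = 0.131 with an estimated correlation. The other intracellular response list, which shares pals-11 and pals-12 with the pals list, had a median of 0.0312 in JU1580. Its adjusted p was 0.524 in camera with an estimated correlation and 0.227 with fry. With the germline covariate its median was -0.0401 (camera adjusted p = 0.0964). At an adjusted p under 0.01, N2 and JU1580 shared 1 higher probe set and JU1580 and rde-1 shared 6. Over called probe sets only, the changes of N2 and JU1580 correlated at -0.22 and those of N2 and rde-1 at 0.82. The germline covariate is built from the oocyte and germline lists, so by construction it takes up their change: oocyte medians became 0.0285 in JU1580, 0.0467 for JU1580 against N2, 0.0451 for rde-1 against N2 and -0.0253 for JU1580 against rde-1, and in N2 the muscle and neuron medians became 0.0413 and 0.0299. Centring moved the median of all probe sets by over 0.1 in 1 comparison, JU1580 against N2, from -0.08 to -0.21.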

Other observations

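Several genes that rose in infected JU1580 were already high in uninfected rde-1. Of 91 probe sets higher in uninfected rde-1 than in uninfected N2, 19 were among the 543 higher in infected JU1580, against 2.19 by chance (one-sided Fisher's exact test, p = 4.76e-13), and 1 was among the 87 lower there. Y47H10A.5 was higher by 3.77 ± 0.28 (SE, n = 3 and 4) in uninfected rde-1 and rose by 3.18 ± 0.30 (n = 3 and 3) in infected JU1580, B0024.4 by 2.82 ± 0.39 and 4.61 ± 0.41, and B0348.2 by 2.15 ± 0.28 and 4.51 ± 0.30. The overlap was looked for after these values were seen, and the 2 contrasts have no array in common.

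Genes that rose on infection often lie beside each other. In rde-1, 15 neighbouring pairs were called higher, where 10000 random draws of as many measured genes gave a median of 0 and at most 4 (permutation p = 0.0001, the smallest these draws allow). Among them were F26F2.1, F26F2.3, F26F2.4 and F26F2.5, the pair ddn-1 and B0507.8, and pals-5 beside pals-6. Of the 417 placed genes lower in uninfected JU1580, 41 pairs were neighbours against a median of 10 and at most 25. With probe sets of a single transcript only, 284 genes were placed. Of these, 16 pairs were neighbours against a median of 5 and at most 16 (permutation p = 0.0002). Paralogues often lie side by side and can share probes, which may account for part of these counts. Fewer placed genes also give fewer pairs, so the smaller number, 16, is no evidence of shared probes. These neighbour tests were fixed before their results were seen.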
